A study of Homo sapiens with 5 samples.

How the data were processed

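RNA of SK-MEL28 melanoma cells was measured on 5 two-colour spotted oligonucleotide arrays, 3 for cisplatin and 2 for cisplatin with electroporation. Per the labels, total RNA was amplified as amino allyl RNA and dye-coupled, with treated cells in Cy5 and untreated cells in Cy3 on every array. Each scanner file as deposited holds the raw foreground intensity and the local background intensity of every spot in both channels, with no normalization, per the file headers. The scanner, its software, spot positions, spot flags and scan dates are not given in the sources used here. No header says which channel is which dye. The first channel was read as Cy3 and the second as Cy5, because the channels are numbered in this order in the labels and because the authors' value table follows the log2 ratio of the second over the first on all 5 arrays. That table holds a log2 ratio per probe, normalized by the authors with a method not given in the sources used here. It lists 2560 probes, of which 1281 have a value on every array, and 488 probes of the scanner files have no row in it. It served as an alternative only.

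Grouping followed the sample titles and the treatment labels, and untreated RNA on the same array was the reference for each treated sample. The 12788 spots of an array represent 3048 probes, 2900 with 4 spots, 147 with 8 and 1 with 12. Gene symbols came from the gene identifiers listed for the probes, which named 2192 probes with 1 gene each and 856 probes with none; 2078 genes were named, 90 of them by more than 1 probe. No genome build is given for the probes, so positions in the genome are left out.

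Starting from the median foreground of each spot, the background was corrected with limma's normexp method (offset 50) and the log2 ratios were normalized by loess within each array (span 0.3). The mean over the spots of a probe gave 1 value per probe and array. The offset draws ratios toward 0, most for dim probes. A probe counted as above background in a channel if at least 0.5 of its spots exceeded the local background by 2 standard deviations. All probes were tested, dim ones included.

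Both group means against 0 and the difference between groups were tested in 1 limma model over the 5 arrays, with 3 residual degrees of freedom and a prior worth 2.47 more. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the 3048 probes with a threshold of 0.05. No array had its dyes exchanged. The difference between treatments is free of a dye preference that is constant per probe, and the comparisons with untreated cells are not. The number of arrays limits the precision. Gene lists, 21 of functions and 5 of cell type markers, were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. The 25 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01) on the brightest probe of each gene, adjusted over the lists. The fibroblast list had 4 measured genes and was not tested as a list. One further list, which was tested, and some fixed genes are not reported here. Members of a list were also adjusted over the list alone. This step was not among the tests fixed beforehand, and it is less strict than the test over all probes.

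The rule for named genes had 3 parts. The first took up to 12 genes in each direction past the test whose arrays went the same way, filled to 12, where fewer passed, with the largest ratios among probes above background on every array. For the difference it asked that every array of 1 group lay above every array of the other. The second took up to 4 members per list with the largest ratio, of which the text names a selection, and the third a fixed set of 34 genes. Genes past the test adjusted over the list alone that fell outside these parts are named as chosen after their values were seen.

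Alternatives covered the background correction (none, offset 0, plain subtraction), median centring without loess, scale normalization between arrays, a filter on dim probes, the median of spots, the authors' value table, single spots with the array as a random block, only the arrays of the group compared, a trended and robust variance, array weights, 1 probe per gene, a replicate block, each array left out in turn, an estimated correlation in camera, and fry. Added after the data were seen were the mean foreground, only the first 3 listed spots of each probe, and the second electroporation array without its last listed spots. Print-tip loess, a rule on flagged spots and a block for scan date or slide could not be run without positions, flags and dates.

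The procedure was tested on simulated data built on the measured intensities (seed 7). In these data 200 probes above background were changed, and each probe was varied between arrays by its residual spread. That spread came from ratios already drawn toward 0 by the offset, and the simulated processing drew it toward 0 again. The simulated arrays can thus vary less than the measured ones, and the recovered shares can be too high. Changes of 0.5, 1 and 2 in log2 were recovered for 56.7%, 91% and 98.5% of changed probes in the cisplatin comparison, for 55.2%, 82.1% and 98.5% in the combination, and for 26.9%, 55.2% and 89.4% in the difference. Between 8 and 12 unchanged probes were called per comparison. The median estimate of a change of 1 was 0.696 in the cisplatin comparison, so the processing shrinks a true change. Genes named for the largest ratios were picked on those ratios, which works the other way, and the balance was not tested. Results were computed with R 4.3.3, limma 3.58.1 and statmod 1.5.0.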

Results

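SK-MEL28, an established human melanoma cell line, was treated with cisplatin, a platinum drug that crosslinks DNA, or with cisplatin combined with electroporation, in which short electric pulses open the cell membrane to the drug. The combination is known as electrochemotherapy. RNA of treated cells was labelled with Cy5 and RNA of untreated cells with Cy3, and both were hybridised to the same spotted oligonucleotide array. There were 3 arrays for cisplatin and 2 for cisplatin with electroporation. Per the labels, electroporation used 8 pulses of 100 µs at 1300 V/cm and 1 Hz. The cisplatin dose and the treatment time of the RNA samples are not given in the sources used here. The question addressed was which apoptosis- and cancer-related genes respond to each treatment, in a study of whether electrochemotherapy alters the metastatic behaviour of melanoma cells.

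Every array held 12788 spots for 3048 probes, with at least 4 spots per probe, and 2078 genes were named. Between 1535 and 1843 probes per array stood above background in the Cy3 channel and between 1216 and 1824 in the Cy5 channel. In at least 1 channel on every array, 1461 probes representing 1196 named genes did so. Across genes, the log2 ratios of the arrays correlated with r between 0.17 and 0.55, and the electroporation arrays with each other at r = 0.22; genes are not independent replicates. The number of arrays limits the precision: for these probes above background, the median 95% confidence interval of a log2 ratio reached 0.14 to either side for cisplatin and 0.18 for the combination. These intervals are for the ratios as processed, which shrink a true change. No array had the dyes exchanged, so a dye preference of a single probe remained in its ratio to untreated cells. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Values below are log2 ratios of treated over untreated cells with the standard error (SE) from limma. Like the intervals above, the SE draws on the spread within both treatments, so for the combination it also rests on the cisplatin arrays.

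Cisplatin alone was compared with untreated cells over 3 arrays. The lowest ratio of a named gene was that of EEF1A1, a translation elongation factor, at -0.64 (SE 0.084, n = 3), followed by RPL31, a protein of the large ribosomal subunit, at -0.59 (SE 0.11). The highest was that of CLEC3B, the plasminogen-binding protein tetranectin, at 0.53 (SE 0.21), with single arrays from 0.075 to 1.19. CCNF, which encodes cyclin F, stood at 0.48 (SE 0.066) and was above 0 on every array. So were TNFSF4, the OX40 ligand, at 0.47 (SE 0.11) and the chromatin protein HMGB2 at 0.47 (SE 0.11), as well as the tweety family membrane protein TTYH1 at 0.45 (SE 0.12) and the retinoblastoma-related RBL2 at 0.43 (SE 0.11). TTYH1, RBL2 and CLEC3B ranked 1, 2 and 3 in brightness among 2078 genes, with mean log2 intensities of 15.5, 15.3 and 15.2. They lie at the upper end of the loess fit, which limits what their ratios show. CORT, WNT2, IGLL1 and KRT19 ranked 4, 7, 8 and 10, while ACTB ranked 316 and GAPDH 319. The pigment cell genes TYRP1 and MLANA ranked 156 and 575. Whether a probe measures only the gene it is named for was not tested, which limits the reading of all named genes. Negative on every array were also the receptor tyrosine kinase RET at -0.49 (SE 0.26) and the lipid-antigen presenting CD1B at -0.48 (SE 0.082). The same held for the quinone oxidoreductase TP53I3 at -0.47 (SE 0.20) and the cytochrome P450 gene CYP2A7 at -0.46 (SE 0.11). A brighter second probe of EEF1A1 read -0.32, and the other probes of TP53I3, which are dimmer, read between -0.080 and 0.057.

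The limma test called 0 of 3048 probes after cisplatin at an adjusted p under 0.05, and the smallest adjusted p was 0.106. An unadjusted p under 0.05 was reached by 337 probes, 151 higher and 186 lower, where chance alone would give 152. Other settings called 4 probes without background correction and 1 in the authors' own value table, EEF1A1 among both, and 132 when single spots were treated as separate measurements. The last setting counts spots of 1 array nearly as independent (fitted correlation within an array 0.087), although they share 1 hybridisation. Its calls, here and below, overstate the replication.

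Damage and death genes had small ratios after cisplatin, but many were dim, and the offset holds dim ratios near 0. In at least 1 channel on every array, 2 of 9 caspases and adaptors and 5 of 13 BCL2 family genes stood above background. The same held for 13 of 31 death receptor genes, 11 of 18 anti-apoptotic genes and 18 of 28 DNA repair genes. The small medians therefore do not show a lack of response. None of 13 BCL2 family and mitochondrial death-promoting genes passed the test over all probes or adjusted over the list alone (median 0.017), with the nuclease ENDOG at -0.21 (SE 0.077) and the apoptosome scaffold APAF1 at 0.12 (SE 0.059). No member of 9 caspases and their adaptors passed either (median 0.0074). Among 18 anti-apoptotic genes (median 0.018), 1 passed adjusted over the list alone: TNFAIP3, the NF-kB inhibitor A20, at 0.24 (SE 0.030), positive on each array. NAIP stood at -0.12 (SE 0.039) and BIRC5, which encodes survivin, at -0.079 (SE 0.030). TNFAIP3 was also the 1 gene past the test adjusted over the list alone among 18 genes of the NF-kB pathway (median 0.029). Of 31 death receptors, TNF ligands and adaptors (median 0.017) none passed; TNFRSF14, the herpesvirus entry mediator, read -0.36 (SE 0.095) and TNFRSF9 0.19 (SE 0.058). None of 28 DNA repair genes passed (median 0.015). Among them were the end-joining ligase LIG4 at 0.15 (SE 0.097), the end-joining factors XRCC6 at -0.12 (SE 0.046) and PRKDC at -0.11 (SE 0.042), and the excision repair helicase ERCC2 at -0.13 (SE 0.054).

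Cell cycle genes went both ways, and of 35 measured (median 0.0038) none passed the test over all probes or adjusted over the list alone. E2F3 stood at 0.40 (SE 0.092), the mitotic phosphatase CDC25C at 0.35 (SE 0.11), the mitotic kinase AURKB at 0.31 (SE 0.073) and CCNB1, cyclin B1, at -0.30 (SE 0.053). The RAS regulator NF1 read 0.19 (SE 0.058) among 18 cell cycle inhibitors and tumour suppressors (median 0.0011), of which none passed. Among genes of adhesion and spread, none passed of 24 integrins and adhesion genes (median 0.012), 12 extracellular matrix genes (median -0.024), 25 matrix proteases and inhibitors (median -0.0052), 7 metastasis suppressors (median -0.084) and 14 metastasis-promoting genes (median -0.0061). Examples were ITGA7, the integrin alpha chain of laminin receptors, at 0.27 (SE 0.067), ITGB4 at -0.26 (SE 0.11), and L1CAM at -0.18 (SE 0.070). The laminin chains LAMB3 and LAMB1 read -0.22 (SE 0.065) and 0.15 (SE 0.036), the protease inhibitor TIMP3 -0.11 (SE 0.040), and CD82, a tetraspanin known as a metastasis suppressor, -0.26 (SE 0.076). CD44, a hyaluronan receptor, read 0.12 (SE 0.047) on its brightest probe, and this ratio was negative with median centring in place of loess. Dimmer CD44 probes read -0.062 and 0.027.

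None of 20 immediate early and stress response genes passed after cisplatin (median -0.0043). JUND stood at 0.27 (SE 0.078), the heat shock gene HSPA1B on its brightest probe at 0.20 (SE 0.074) and ATF4, a transcription factor of the integrated stress response, at -0.19 (SE 0.068). Of 12 genes of oxidative stress and drug handling (median 0.012) none passed; the quinone reductase NQO1 read -0.35 (SE 0.12) and the glutathione transferase GSTP1 -0.20 (SE 0.062). Pigment cell genes had positive medians, 0.12 over 5 melanocyte markers and 0.032 over 14 lineage genes that include these 5, with no member past the test. The pigment enzyme TYRP1 stood at 0.19 (SE 0.058), the lineage transcription factor MITF at 0.18 (SE 0.069), MLANA at -0.072 (SE 0.080) and S100B at -0.25 (SE 0.13). Of 9 housekeeping genes (median -0.096), GAPDH passed adjusted over the list alone at -0.28 (SE 0.059), beside YWHAZ at -0.22 (SE 0.084) and RPL32 at -0.20 (SE 0.077). The list's own test gave an adjusted p of 0.190 with limma's camera and passed at 0.0403 without the third cisplatin array. TIE1, an endothelial receptor, at -0.23 (SE 0.054), passed adjusted over the list alone among 6 endothelium markers (median -0.049) but not among 24 angiogenesis genes (median 0.00023). The medians were -0.0093 for 31 growth factor and kinase signalling genes, -0.014 for 7 chromatin genes, -0.022 for 6 epithelium markers and -0.0070 for 6 leukocyte markers. By camera 0 of 25 lists passed for cisplatin, and 1 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move one way on balance, called 0, and its mixed form, which counts change in either direction, called 8. The median, the mean and the camera direction differed in sign in 5 of the lists.

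Of 34 genes chosen beforehand as likely responders or markers, 27 were measured, and 14 of them stood above background on every array. Among the other 13 were the cell cycle inhibitor CDKN1A, with -0.015 (SE 0.037) after cisplatin and 0.022 (SE 0.046) after the combination, and BAX with 0.098 (SE 0.040) and 0.026 (SE 0.049). BCL2, BCL2L1, MCL1, JUN, FOS, MYC, MMP9, TIMP1, ITGB3, MCAM and ERCC1 lay between -0.072 and 0.067 after cisplatin and between -0.21, for TIMP1, and 0.039 after the combination. On the second electroporation array TIMP1 read -0.49 over all spots and 0.28 without its last listed spot, which was faulty. Signal over background was low for these 13 transcripts, which limits what their ratios show. Above background, the damage-inducible GADD45A read -0.0097 (SE 0.048) after cisplatin and 0.034 (SE 0.058) after the combination, CASP9 -0.028 and -0.16, the gelatinase MMP2 -0.047 and 0.077, ITGAV 0.026 and 0.052, and the neural cadherin CDH2 0.13 and 0.067. MDM2, FAS, CASP8, ATF3 and VEGFA were not analysed here, since no probe was matched to them.

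**Figure D1:**
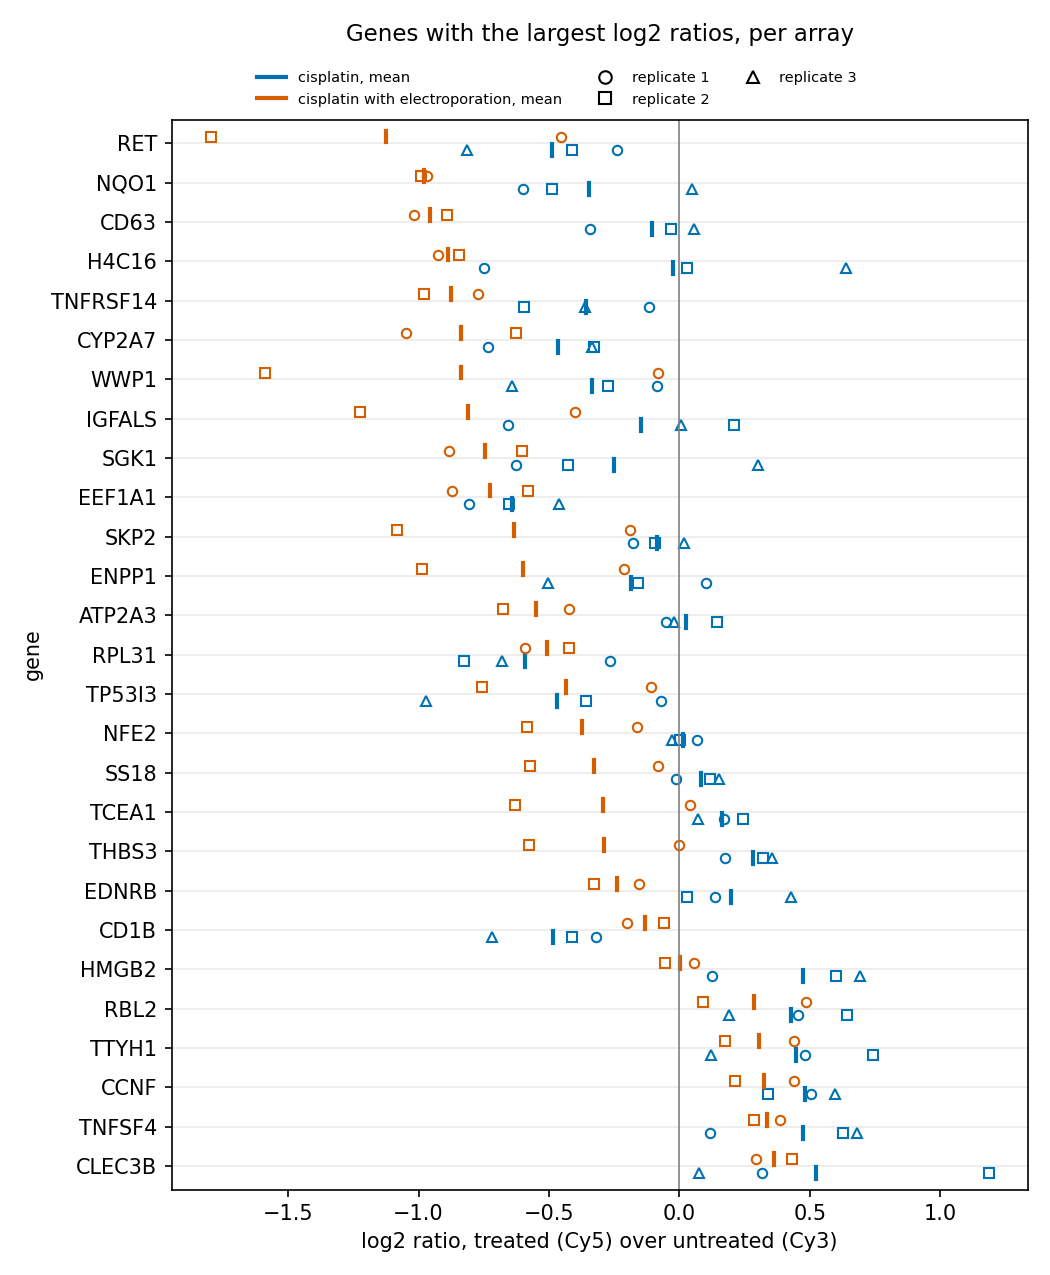
Log2 ratio of treated over untreated cells (horizontal axis) for the genes with the largest ratios in any comparison (vertical axis), 1 symbol per array and a bar at the mean of each treatment. For CD63 the electroporation arrays sit at -1.02 and -0.89, below the cisplatin arrays, which lie between -0.34 and 0.054.

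Cisplatin with electroporation was compared with untreated cells over 2 arrays. The largest ratios were negative. RET stood at -1.13 (SE 0.31, n = 2), with -0.45 and -1.80 on the single arrays. The SE comes from the model that includes the cisplatin arrays. It can understate the spread between the electroporation arrays, as it does for RET. NQO1 read -0.98 (SE 0.15), the lysosomal and melanosomal tetraspanin CD63 -0.96 (SE 0.099), and TNFRSF14 -0.88 (SE 0.12). The histone gene H4C16 stood at -0.89 (SE 0.30) on its brightest probe and between -0.28 and 0.11 on 5 dimmer ones. CYP2A7 read -0.84 (SE 0.14), the insulin-like growth factor carrier IGFALS -0.81 (SE 0.26), the serum- and glucocorticoid-regulated kinase SGK1 -0.74 (SE 0.22), EEF1A1 -0.73 (SE 0.10), with -0.47 (SE 0.19) on its brighter probe, and the ectonucleotidase ENPP1 -0.60 (SE 0.21). On the second array IGFALS read -1.225 and ENPP1 -0.99, so for both the first array lay above the mean. A dimmer IGFALS probe read -0.26 (SE 0.15). For the ubiquitin ligase genes WWP1 and SKP2, at -0.84 (SE 0.35) and -0.64 (SE 0.20), the second array carried the mean: WWP1 read -0.082 and -1.59, and SKP2 -0.19 and -1.08. The highest ratio was that of a dimmer probe of the heat shock gene HSPA1B at 0.46 (SE 0.068), named after its value was seen, while the brighter HSPA1B probe read 0.027 (SE 0.091). The dimmer probe was called in the authors' value table (limma adjusted p = 0.0396) and with single spots (0.00130).

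The limma test called 0 of 3048 probes for the combination, with a smallest adjusted p of 0.0932, that of CD63. An unadjusted p under 0.05 was reached by 304 probes, 91 higher and 213 lower, where chance would give 152. With median centring in place of loess 1048 probes reached it, and 35 passed, all of them lower. With all arrays kept, between 1 and 91 probes passed in 6 other settings, and CD63, NQO1, TNFRSF14, CYP2A7, EEF1A1 and LAMB3 were all called in 4 of them, with dim probes left out (11 probes), in the authors' value table (8), without background correction (10) and with single spots (91). TNFRSF14 and LAMB3 were also called with median centring. Without the third cisplatin array 1 probe passed, that of NQO1. Without the first electroporation array 93 passed, with the second then standing alone and assumed to vary like the cisplatin arrays, and with genes that rest on its faulty spots, such as NFE2, among them.

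Housekeeping genes were lower than in untreated cells on both electroporation arrays for 9 of 9 measured, with a median of -0.30, and the list passed with limma's camera (adjusted p = 5.603e-06). The adjusted p was 0.687 with an estimated correlation and 0.0546 with fry. Adjusted over the list alone 5 of the 9 passed: the glycolytic enzymes LDHA at -0.45 (SE 0.073) and GAPDH at -0.38 (SE 0.073), the prolyl isomerase PPIA at -0.45 (SE 0.10), and the cytoskeletal genes ACTB at -0.30 (SE 0.085) and TUBA1B at -0.30 (SE 0.080), the last of them named after its value was seen. On the second electroporation array, ACTB read -0.22 over all spots and 0.17 without its last listed spots, some of which were faulty.

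Among cell cycle genes 3 of 35 passed adjusted over the list alone after the combination: CCNB1 at -0.42 (SE 0.065), CDK2, the kinase of S-phase entry, at -0.31 (SE 0.040), and E2F1 at -0.27 (SE 0.054), which was named after its value was seen. On the second electroporation array, E2F1 read -0.32 over all spots and 0.012 without its last listed spots. The mitotic kinase PLK1 stood at -0.54 (SE 0.25) with 0.019 on the first array and -1.10 on the second, and CDC25C at 0.33 (SE 0.13). The list's median was -0.016, and it passed with limma's fry (adjusted p = 0.0289) but not with camera (0.766). Of the 12 extracellular matrix genes (median -0.023) 2 passed adjusted over the list alone, LAMB3 at -0.54 (SE 0.080) and the proteoglycan DCN at -0.22 (SE 0.050); SPARC read 0.14 (SE 0.051). No integrin or adhesion gene passed (median 0.021): ITGA7 read 0.34 (SE 0.082) and ITGB1, the common beta chain, -0.37 (SE 0.17) with 0.0071 and -0.74 on the single arrays. No matrix protease or inhibitor passed (median -0.014), with MMP10 at 0.17 (SE 0.048) and TIMP2 at -0.53 (SE 0.20), the latter with -0.070 and -0.99 on the single arrays. None of the metastasis suppressors (median -0.026) or metastasis-promoting genes (median 0.010) passed, with the epithelial cadherin CDH1 at -0.15 (SE 0.052) and CD44 at 0.13 (SE 0.057). Among angiogenesis genes (median -0.0092) 1 passed adjusted over the list alone, TIE1 at -0.40 (SE 0.067), and the semaphorin receptor NRP2 read 0.26 (SE 0.086).

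In the death receptor list (median 0.0027) TNFRSF14 passed adjusted over the list alone, and TNFSF4 stood at 0.34 (SE 0.14). None of the other death and damage lists had a member past the test. TP53I3 read -0.43 (SE 0.24), and of the BCL2 family and mitochondrial genes (median 0.014), BNIP3 read 0.14 (SE 0.052). Among anti-apoptotic genes (median 0.036) TNFAIP3 stood at 0.15 (SE 0.037), BIRC5 at -0.15 (SE 0.037) and the survival kinase AKT1 at -0.29 (SE 0.14), with 0.022 and -0.60 on the single arrays. The caspases, of which 2 of 9 stood above background on every array, had a median of 0.021. DNA repair genes (median -0.0063) included the replication protein RPA3 at -0.37 (SE 0.088) and the ligase LIG3 at -0.19 (SE 0.045). NF1 read 0.27 (SE 0.071) among cell cycle inhibitors and tumour suppressors (median 0.0094). NQO1 passed adjusted over the list alone among oxidative stress and drug handling genes (median -0.056), beside GSTP1 at -0.30 (SE 0.077) and the thioredoxin reductase TXNRD1 at -0.14 (SE 0.051). JUND at 0.28 (SE 0.095), the endoplasmic reticulum chaperone HSPA5 at -0.25 (SE 0.073) and the heat shock co-chaperone DNAJB1 at 0.21 (SE 0.061) had the largest values above background in the stress list (median 0.0029), taking the brightest probe of each gene. With median centring in place of loess the ratios of TNFAIP3, NF1, ITGA7, SPARC, CD44, MMP2, NRP2 and DNAJB1 after the combination were negative.

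Pigment cell genes had negative medians after the combination, -0.048 over 5 melanocyte markers and -0.059 over the 14 lineage genes. MLANA, a melanosome antigen, stood at -0.38 (SE 0.098), S100B at -0.36 (SE 0.16) with -0.034 and -0.69 on the single arrays, and MITF at -0.082 (SE 0.085). Epithelium markers had a median of -0.13 and passed with limma's fry (adjusted p = 0.0281) but not with camera (0.345). Endothelium markers had a median of -0.041, and TIE1 passed adjusted over the list alone. Leukocyte markers had a median of -0.15, with -0.0021 and -0.22 on the single arrays, and ITGAM passed adjusted over the list alone at -0.51 (SE 0.13). On the second electroporation array ITGAM read -0.65 over all spots and 0.025 without its last listed spot. For the remaining lists the medians were -0.043 for growth factor and kinase signalling, 0.019 for the NF-kB pathway and -0.0020 for chromatin genes, with no member past the test. By camera 1 of 25 lists passed, by fry 2, by its mixed form 10 and with an estimated correlation 0. The median, the mean and the camera direction differed in sign in 8 lists.

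**Figure D2:**
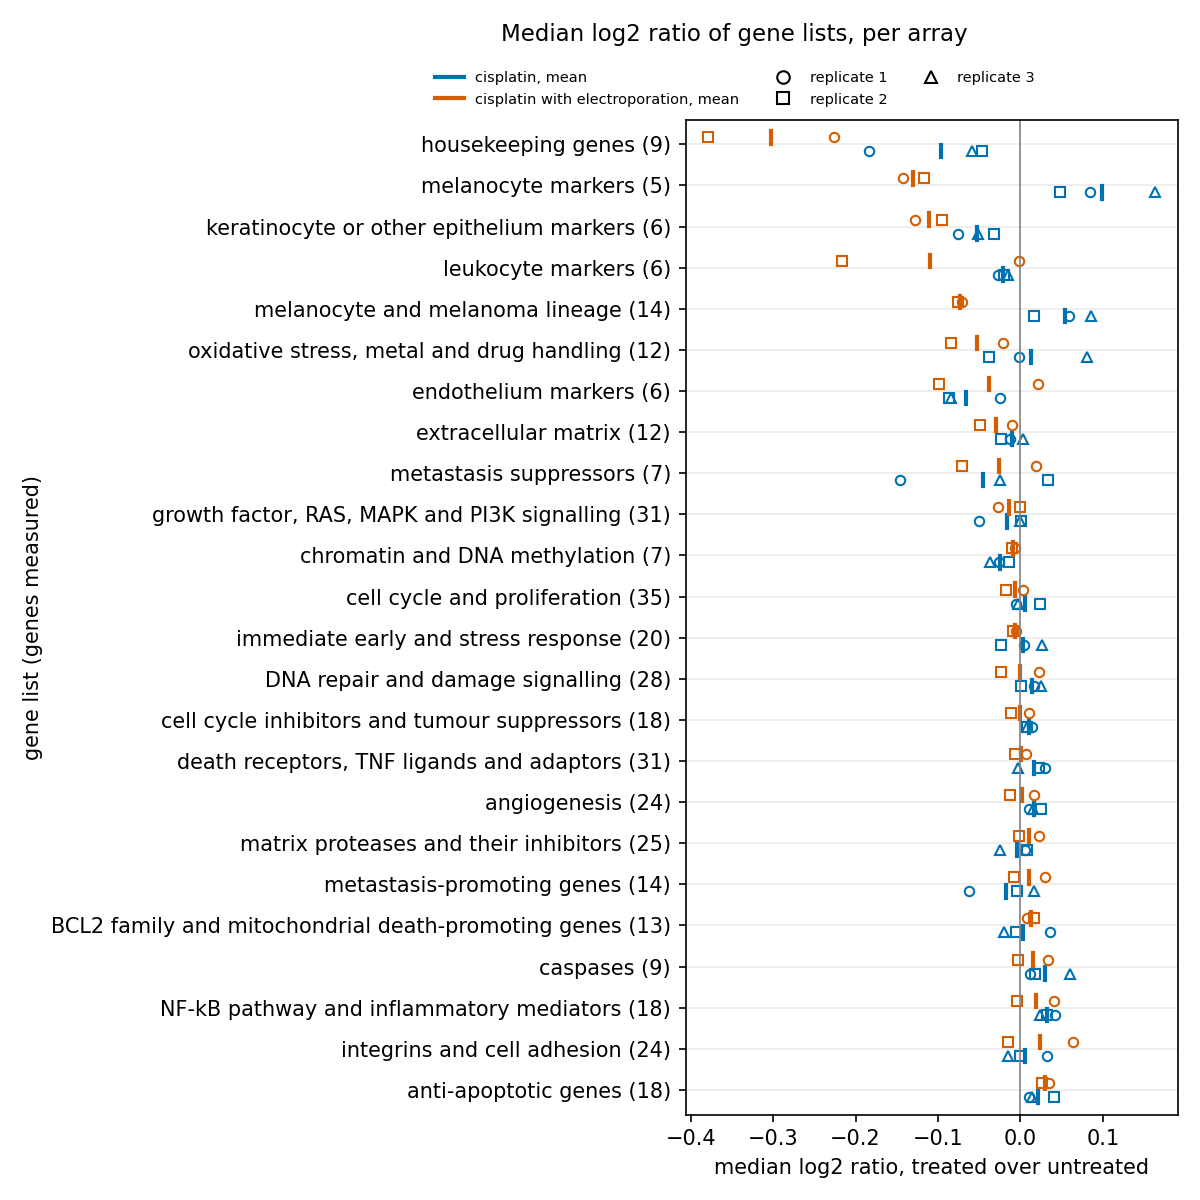
Median log2 ratio of treated over untreated cells (horizontal axis) over the measured genes of the lists shown (vertical axis, with the number of genes), 1 symbol per array and a bar at the mean of each treatment. Housekeeping genes sit at -0.23 and -0.38 on the electroporation arrays and between -0.18 and -0.046 on the cisplatin arrays, and melanocyte markers at -0.14 and -0.12 against 0.048 to 0.16.

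The contribution of electroporation was addressed by comparing the combination with cisplatin alone, 2 arrays with 3. Among genes with every array of 1 treatment above every array of the other, the largest differences were negative. CD63 differed by -0.85 (SE 0.13), the brightest H4C16 probe by -0.86 (SE 0.39) and NQO1 by -0.63 (SE 0.20). The endoplasmic reticulum calcium pump ATP2A3 differed by -0.58 (SE 0.10), SKP2 by -0.55 (SE 0.26), TNFRSF14 by -0.52 (SE 0.15), HMGB2 by -0.47 (SE 0.18) and EDNRB, the endothelin receptor of pigment cell development, by -0.44 (SE 0.13). THBS3 at -0.57 (SE 0.17), TCEA1 at -0.46 (SE 0.20), SS18 at -0.41 (SE 0.15) and NFE2 at -0.39 (SE 0.13) rested on 1 faulty spot each, the last listed on the second electroporation array: without it that array read 0.11, 0.060, -0.022 and -0.023 in this order.

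The limma test called 0 of 3048 probes for the difference between treatments, with a smallest adjusted p of 0.994, and 107 had an unadjusted p under 0.05, 39 higher and 68 lower, where chance would give 152. That count was 188 with median centring and with single spots, 291 without the first electroporation array, and below 152 in the other settings. Treating single spots as separate measurements called 3 probes, those of ATP2A3, CDK2 and EDNRB, and 47 passed without the first electroporation array, THBS3, TCEA1 and NFE2 with their faulty spots among them. The median 95% confidence interval of a difference reached 0.23 to either side for probes above background. Arrays with the same replicate number, which had similar Cy5 background (SD 13.6 and 13.5 in replicates numbered 1, 5.40 and 5.77 in those numbered 2), gave within-pair differences of -0.68 and -0.86 for CD63, -0.37 and -0.50 for NQO1, -0.38 and -0.82 for ATP2A3 and -0.29 and -0.36 for EDNRB. The rule that named these genes put both electroporation arrays below every cisplatin array. The negative sign of these differences was thus fixed by the choice of genes and is not separate evidence.

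Housekeeping genes were lower after the combination than after cisplatin by camera (median difference -0.24, adjusted p = 0.00779), with an adjusted p of 0.674 with an estimated correlation and 0.473 with fry, and none of the 9 passed adjusted over the list alone. LDHA differed by -0.36 (SE 0.094), ACTB by -0.33 (SE 0.11) and PPIA by -0.32 (SE 0.14). The ACTB difference rests in part on faulty spots: the second electroporation array read -0.22 for ACTB over all spots and 0.17 without the last listed ones. The median difference was -0.032 between the arrays numbered 1 and -0.23 between those numbered 2, and -0.19 with the replicate number as a block (adjusted p = 0.0227). The call was lost with a smaller difference without the second electroporation array (-0.16, adjusted p = 0.278), in the authors' value table (-0.19, 0.0730) and over the first 3 listed spots (-0.077, 0.152). It was also lost with the other background corrections (0.0553 to 0.378), where the difference lay between -0.28 and -0.25.

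Among cell cycle genes CDK2 passed adjusted over the list alone for the difference, at -0.34 (SE 0.052); AURKB read -0.36 (SE 0.12) and PLK1 -0.53 (SE 0.32). No other list had a member past the test. Pigment cell genes differed by medians of -0.18 over the melanocyte markers and -0.081 over the lineage genes, each with a camera adjusted p of 0.0559. The markers are all part of the lineage list, so the tests of these lists are not separate evidence. Both passed with the median of spots, with single spots, without the second cisplatin array and over the first 3 listed spots, and the lineage genes also without the last listed spots of the second electroporation array. MLANA differed by -0.30 (SE 0.13), MITF by -0.27 (SE 0.11) and TYRP1 by -0.18 (SE 0.092). The oxidative stress and drug handling genes had the same adjusted p (median -0.092), with the superoxide dismutase SOD1 at -0.18 (SE 0.049). They passed in the authors' value table, with dim probes left out, with the median of spots, with single spots, and without the first or the second cisplatin array. Of adhesion and matrix genes, LAMB3 differed by -0.32 (SE 0.10), LAMB1 by -0.24 (SE 0.056), DCN by -0.18 (SE 0.065), MMP10 by 0.20 (SE 0.062) and ITGB1 by -0.37 (SE 0.22). Among damage genes RPA3 differed by -0.32 (SE 0.11) and BNIP3 by 0.16 (SE 0.067), and among endothelium markers TIE1 by -0.17 (SE 0.086). The medians of all 25 lists lay between -0.24 and 0.026, and the camera adjusted p of those outside the housekeeping, pigment cell and oxidative stress lists between 0.238 and 0.971. Both fry and its mixed form called 0 lists. The median, the mean and the camera direction differed in sign in 11.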

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

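The tests without the last listed spots and over the first 3 listed spots were chosen only after the result was seen, and the test against random lists was planned. One result stood out because the 2 treatments differed by a test of the difference itself: the median of the 9 housekeeping genes differed by -0.24 between the combination and cisplatin alone. The adjusted p of limma's camera was 0.00779, and it ranged from 0.000708 to 0.674 over the alternatives. The medians on the single arrays were -0.18, -0.046 and -0.058 for cisplatin and -0.23 and -0.38 for the combination. Before normalization the median log2 ratio over all spots was also lowest on the electroporation arrays, at -0.35 and -0.52, against -0.18, -0.0061 and 0.087 for cisplatin. Whether the list follows this array-wide shift was not tested.

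An intensity trend left after loess could lower bright genes, but the median of -0.30 against untreated cells lay at percentile 0.17 of 10000 random lists matched on mean intensity, whose medians lay between -0.17 and 0.075 for the central 95%, which argues against a trend. That list call itself was lost with an estimated correlation (adjusted p = 0.687) and with limma's fry (0.0546). On the second electroporation array some last listed spots did not match the other spots of their probe, and without them the median against untreated cells was -0.23 (adjusted p = 0.000377 with limma's camera), so this fault does not explain that result. For the difference between treatments, in which a constant dye preference cancels, the fault cannot be told apart from a response to electroporation. Without those spots the difference was -0.16 (camera adjusted p = 0.0452), and over the first 3 listed spots of every array -0.077 (0.152). Electroporation, the biological explanation that the design offers, stays open and untested. No array here had pulses without the drug. An effect of the pulses therefore cannot be told apart from one of more drug entering the cells.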

How the results depend on the processing

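Choices and their alternatives were set before the data were examined, except for the mean foreground, the first 3 listed spots and the second electroporation array without its last listed spots, which were chosen after seeing the data. The adjustment over the list alone was not among the choices fixed beforehand either. Of the values of named genes under the alternatives, 3275 stayed the same or moved little, 324 moved further, 100 newly passed the test and 14 reversed. None could lose a call, since the main setting called 0 probes. Of list medians 1682 stayed or moved little, 41 moved further, 18 newly passed, 10 no longer passed and 0 reversed. A list could count as reversed only if it passed in the main setting, which only the housekeeping list did. Sign changes in the medians of other lists were thus not counted as reversed. Where a value changed, the cause was not tested. The counts that moved were, for probes after cisplatin (0), 4 without background correction, 1 in the authors' value table and 132 with single spots; for probes after the combination (0), 10 without background correction, 35 with median centring, 1 with scale normalization, 11 with dim probes left out, 8 in the authors' value table and 91 with single spots; and for probes of the difference (0), 3 with single spots. Lists after the combination (1) numbered 0 with an estimated correlation and 2 with fry. Lists of the difference (1) numbered 0 without background correction, with offset 0, with subtraction, with an estimated correlation and with fry, 2 with dim probes left out, with the first 3 listed spots and without the last listed spots, and 4 with the median of spots and with single spots. With each array left out in turn, probes after cisplatin numbered 0 to 0, after the combination 0 to 93 and in the difference 0 to 47, and lists 0 to 1, 1 to 1 and 0 to 4. A lone electroporation array was then assumed to vary like the cisplatin arrays.

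The labels do not say that arrays with the same replicate number belong together. The deviations of these pairs from their group means correlated at 0.269 and 0.0917, and those of the third cisplatin and second electroporation arrays at 0.221. With 2 electroporation arrays their deviations are exact opposites, so these correlations are tied to each other and are not separate evidence of pairing. Ratios of the arrays numbered 1 had the highest r of all pairs (0.552), but those numbered 2 (0.283) lay below the second cisplatin with the first electroporation array (0.340). With that number as a block, probes stayed at 0 in all comparisons and lists at 0, 1 and 1, the housekeeping difference was -0.19 (limma adjusted p = 0.0227, 0.000708 to 0.674 over all alternatives), and no other call changed. With median centring CD44 after cisplatin read -0.0060, and after the combination TNFAIP3 -0.094, NF1 -0.044, ITGA7 -0.0053, SPARC -0.15, CD44 -0.15, MMP2 -0.27, NRP2 -0.037, DNAJB1 -0.14, FOS 0.084 and MYC 0.0022. FOS after the combination read 0.29 with subtraction, and CDKN1A -0.015 with single spots and -0.016 with the first 3 listed spots. The housekeeping median after the combination ranged from -0.60 to -0.20 over the alternatives and its difference from -0.32 to -0.077. Print-tip loess, flagged spots kept, and a block by scan date or slide were not run. Signal over background limits what dim probes can show, since the offset holds their ratios near 0.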

Other observations

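The tests without the last listed spots, the comparison of spots by their place in the listing and the count of shared signs were chosen only after the results were seen.

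Both pigment cell lists had medians above 0 on every cisplatin array and below 0 on both electroporation arrays, but neither passed the test of the difference (adjusted p = 0.0559 each with limma's camera, 0.00644 to 0.674 over the alternatives), and single members overlapped. The median of the 5 melanocyte markers was 0.085, 0.048 and 0.16 on the cisplatin arrays and -0.14 and -0.12 on the electroporation arrays, and the median of the differences of single markers was -0.16 between the arrays numbered 1 and -0.069 between those numbered 2. The 14 lineage genes, which include the 5 markers and so are not separate evidence, had medians of 0.060, 0.016 and 0.086 against -0.070 and -0.075. MITF read 0.13, 0.048 and 0.38 against -0.14 and -0.021, EDNRB 0.13, 0.029 and 0.43 against -0.15 and -0.33, TYRP1 0.27, 0.13 and 0.16 against 0.13 and -0.12, and MLANA -0.046, -0.22 and 0.048 against -0.21 and -0.54. Outside the pigment cell lists, LAMB1 read 0.10, 0.19 and 0.15 against -0.14 and -0.049, CDK2 0.049, -0.030 and 0.056 against -0.33 and -0.30, and SOD1 0.050, 0.085 and 0.12 against -0.083 and -0.11. No cause was tested for these values.

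On the second electroporation array, the fourth listed spot of 274 of the 2900 probes with 4 spots was more than 8 times brighter in Cy3 than the probe's median spot, 9.45% of them, and that of 229 more than 8 times dimmer. The mean correlation of the last listed spots with the other spots of the 2900 probes was 0.461, against 0.805 to 0.809 for the spots listed before. The latter means include the correlation with the last spot, so they do not show that the first 3 spots differ among themselves. On the other arrays the means lay between 0.969 and 0.984. Values of probes without such a bright spot moved as well when last spots were left out, TNFRSF14 from -0.98 to -1.33 and GAPDH from -0.48 to -0.69.

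Of 118 probes below -0.5 on the second electroporation array, 70 had a bright last listed spot, and 48 did not. The 70 could owe their ratio to these spots, whose signal has an origin that was not tested: without the last listed spots their median was -0.038 and 0 stayed below -0.5. The 48 still had a median of -0.62 without those spots, and 36 of them stayed below -0.5, which argues against this fault for most of them. Their median on the first electroporation array was -0.14, with 35 below 0 and 8 below -0.5, and over the cisplatin arrays, which had no pulses, it was -0.13. The first electroporation array thus lay close to the cisplatin arrays for these probes. A response shared by both electroporation arrays cannot be told apart from a peculiarity of the second, since 1 other array is all there is to compare.

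The ratio had the same sign on all 5 arrays for 490 probes, 16.1% where independent arrays would give 6.25%, and for 309 probes above background. Of the 490, 203 were higher and 287 lower than in untreated cells. A dye preference of single genes and a response to cisplatin common to both treatments could each give the 16.1%, and they cannot be told apart, because no array had its dyes exchanged. Other dependence between arrays was not tested. The arrays numbered 1, of different treatments, correlated at r = 0.552, and the 2 electroporation arrays at 0.22.

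Of 90 genes with more than 1 probe, the mean ratios of 2 probes correlated with a Spearman coefficient of 0.209 and their intensities with 0.576. For the 36 genes with both probes above background the coefficients were 0.451 and 0.435. The 4 measured fibroblast markers, too few for a list test, read -0.045 for COL3A1, -0.047 for DCN, 0.070 for FAP and -0.046 for PDGFRA after cisplatin, and 0.029, -0.22, 0.027 and -0.026 after the combination. Before normalization the median log2 ratio of an array was -0.18, -0.0061 and 0.087 for cisplatin and -0.35 and -0.52 for the combination.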
